A study of Homo sapiens with 9 samples.

How the data were processed

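Total RNA of Flip-In-293 cells, 3 samples per group, was amplified, turned into labelled single-stranded cDNA and hybridised to Affymetrix Human Exon 1.0 ST arrays. The deposited values are log2 probe set signals, 1 value per probe set and array, normalised between arrays and summarised by RMA; the submitters' processing notes name Affymetrix Power Tools, RMA and the genome build hg18, and the series description names the Exon Array Computational Tool. Tool versions and further filters are not given in the sources used here. RMA subtracts an estimated background and forces the arrays to 1 distribution, so a change shared by most transcripts cannot be seen, and probe sets with weak signal have compressed changes. The log2 scale was read from the values, with a maximum between 14.8 and 15.2 on all arrays.

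The arrays gave values for 1384231 probe sets. The platform annotation gave 1 gene symbol for 354600 of them, several for 14898 and none for 1014733; probe sets with several were not named. Of 19497 symbols, 16426 were current in RefSeq for GRCh38.p14, 2950 were updated through a synonym that belongs to 1 gene, and 121 were kept as given. Only symbols were taken from there, and no coordinates are printed, because the builds differ. A comparison of the 3' and 5' ends of genes that had been planned was not run, since the order of probe sets along a gene is not given in the sources used here.

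Analyses were run in R 4.3.3 with limma 3.58.1 and version 1.17.8 of the data.table package. Probe sets were kept if their mean over the 9 arrays was at or above the median of all probe sets (6.97), which left 692116, of which 266506 had 1 gene. The gene level was the median over at least 3 kept probe sets (16748 genes). Exon signal was the probe set's value minus the gene level of the same array, for genes with at least 5 kept probe sets (257548 probe sets in 15035 genes). Gene levels, exon signals and single probe sets were each fitted with lmFit and eBayes in 1 model of 3 groups without a block, with 2-sided tests and Benjamini-Hochberg adjustment at 0.05 over all features of a comparison. An exact permutation test of 3 arrays against 3 cannot go below p = 0.1. The median gene level makes 338 probe sets exactly 0 on every array, which weakens the exon test; a run without them was added after the data were examined.

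The 22 gene lists were written beforehand, with markers of other cell types among them, and tested with camera (preset correlation 0.01 and estimated correlation) and fry, each adjusted over the 22 lists and both comparisons with control together (44 tests), and over the 22 lists for the contrast of the targeted groups. Called members are given over all genes and adjusted over the list alone. Lists of genes with known RBFOX exons come from general knowledge and not from these arrays. The named genes follow a rule fixed beforehand. It takes the targets and, per targeted group, the 10 largest rises and 10 largest falls among called genes whose arrays all lie beyond all control arrays. It adds the 5 largest exon shifts each way, up to 2 highest and 2 lowest called members per list, the 5 largest differences each way between the targeted groups, and 5 shared genes and exons. Where no list member was called, the one with the smallest p is eligible. Symbols of unnamed loci were passed over. Because no exon passed the main test, the exon part of the rule was applied to the fit with the mean as gene level, which had been fixed beforehand as a further setting; exons of the RBFOX list were named from their adjustment over the list alone, chosen after the test over all exons had called 0.

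Further settings fixed before the data were examined were no filter or a filter at the upper quartile (8.36), quantile normalisation, centring of arrays, leaving out each array, a replicate block, only the compared groups, a variance trend with robust fitting, a minimum change of 0.5, array weights, the mean as gene level, diffSplice and an estimated correlation. For shared controls, unchanged groups were simulated 100 times. The tests were also tested on simulated data, with 200 changed features among 16748 genes or 257548 exons, for the comparison of the arrays labelled CPSF3 knockdown with control. The gene test recovered 86% of log2 changes of 1 and 28% of those of 0.5, with 14 false calls. The exon test recovered 81% of changes of 2 and 15% of changes of 1, with 10 false calls, and diffSplice recovered 100% and 81% with 1031 false calls. No array was left out of the main results.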

Results

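Total RNA from Flip-In-293 cells, a derivative of the human embryonic kidney line HEK293 with a single integration site, was measured on 9 exon arrays. The cells had been infected with lentivirus carrying 1 of 3 short hairpin RNAs and kept for 10 days: a non-silencing hairpin (control), a hairpin against CPSF3, or a hairpin against RBFOX2. CPSF3 is the endonuclease that cuts pre-mRNA before the poly(A) tail is added, and RBFOX2 is an RNA-binding protein that regulates alternative exons. Each group held 3 arrays. The array reads most exons through separate probe sets, so a gene's overall level and the relative signal of each exon could be tested separately. The series asks how loss of a 3' end formation factor changes the use of internal exons, set against loss of a splicing regulator. Median signal differed by under 0.05 (log2) between arrays. Sample titles call the replicates biological while the series description calls them technical, so p-values measure the spread between these arrays, which may be technical. Errors of differences are SE from the fit over 3 arrays per group, and errors of levels are SD (n = 3).

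The targeted genes were examined first. CPSF3 was at 9.47 ± 0.29 on the control arrays, 9.38 ± 0.19 on the arrays labelled CPSF3 knockdown and 9.71 ± 0.18 on the RBFOX2 knockdown arrays. Its change in the arrays labelled CPSF3 knockdown was -0.09 ± 0.16 (adjusted p = 0.752, limma), with a 95% interval from -0.43 to 0.24, or 74.3% to 118% of the control level. Of its 21 probe sets, 19 had a lower mean there, and 0 were lower at an unadjusted p under 0.05. The label of these arrays is therefore not borne out by the targeted transcript, and they are called arrays labelled CPSF3 knockdown throughout; every direction drawn from them rests on that label. These and the RBFOX2 knockdown arrays are together called the targeted groups. RBFOX2 was at 9.53 ± 0.14 on the control arrays and 8.94 ± 0.11 on the RBFOX2 knockdown arrays, a change of -0.58 ± 0.12 that left 66.7% of the control level (95% interval 56.1% to 79.2%). All 21 RBFOX2 probe sets had a lower mean, 14 of them at an unadjusted p under 0.05. The fall passed the threshold when adjusted over the 2 targets alone (adjusted p = 0.000368) and missed it over all genes (adjusted p = 0.0617). In the arrays labelled CPSF3 knockdown, RBFOX2 differed from control by -0.20 ± 0.12 (adjusted p = 0.296).

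**Figure D1:**
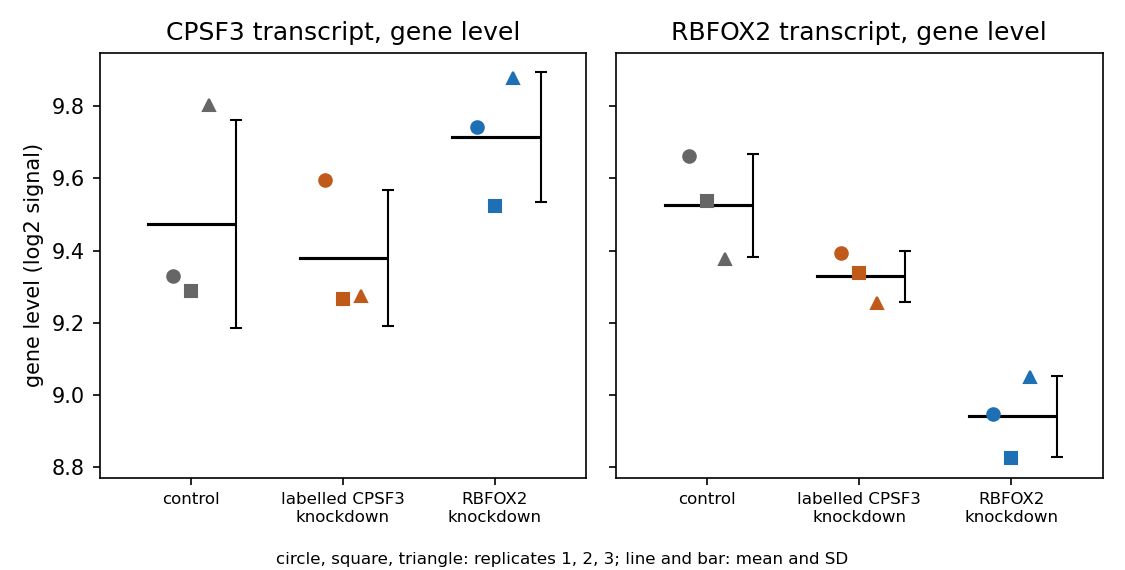
Gene level (log2 signal, vertical axis) of CPSF3 and RBFOX2 on each array by group (horizontal axis); symbols are replicates, the line is the mean and the bar the SD. RBFOX2 lies lower on the 3 RBFOX2 knockdown arrays (mean 8.94) than on the 3 control arrays (9.53), while CPSF3 on the arrays labelled CPSF3 knockdown (9.38) overlaps the control (9.47).

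In the arrays labelled CPSF3 knockdown, 2409 of 16748 genes differed from control, 1675 higher and 734 lower. STC1, a secreted glycoprotein hormone, fell most, at -2.38 ± 0.23 (5.21-fold; adjusted p = 0.000268). TXNIP and ARRDC4, paralogous arrestin-domain genes induced by glucose, changed by -2.28 ± 0.24 and -1.63 ± 0.23. Further large falls were those of DDIT4, an inhibitor of mTORC1 signalling (-1.82 ± 0.12, adjusted p = 5.37e-06), the lipid droplet protein HILPDA (-1.63 ± 0.20), the transcription factors ATF3 (-1.63 ± 0.26) and BHLHE40 (-1.55 ± 0.21), and the cytokine GDF15 (-1.54 ± 0.15). SNHG1, a host gene of small nucleolar RNAs, and the neurite protein gene NRN1 changed by -1.86 ± 0.33 and -1.65 ± 0.15. The largest rises included NCOA5, a nuclear receptor coactivator (1.80 ± 0.23, 3.48-fold), YAE1 (1.73 ± 0.26), the zinc finger genes ZNF480 (1.71 ± 0.23) and ZNF594 (1.58 ± 0.28), and PIGW, an enzyme of GPI anchor synthesis (1.60 ± 0.23). PCF11, a subunit of the cleavage complex itself, rose by 1.57 ± 0.30 (2.96-fold, adjusted p = 0.00595). EPC2, the histone chaperone ASF1A and the dolichol kinase DOLK rose by 1.56 ± 0.31, 1.56 ± 0.27 and 1.55 ± 0.31. The pseudogene PRKXP1 had the highest rise of all (1.87 ± 0.21), which is uncertain because its 3 probe sets may also bind transcripts of the parent gene. Some of these sizes depended on the probe sets used: DOLK and PRKXP1 were at 0.26 and 0.33 and lost their calls without a filter, ZNF594, PCF11 and ZNF480 were at 0.41, 0.83 and 1.03 with the stricter filter, and NRN1 at -0.59 with the mean as gene level. Changes of at least 2-fold numbered 123 upward and 55 downward. The arrays of the groups did not overlap at 31.1% of all genes, against 10% by chance. The count fell to 1082, 1205, 965 and 1466 without control replicate 1, control replicate 2, CPSF3 replicate 1 and CPSF3 replicate 2, and was 4817 with array weights. Control replicate 3 lay nearer to the targeted groups than the other controls did, and without it the count was 3429.

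Lists of RNA processing genes were tested next in these arrays. Of 21 measured mRNA 3' end processing factors 6 rose and 1 fell (10 called when adjusted over the list alone), with a median change of 0.22. PCF11 and CSTF3 (1.40 ± 0.31) led, and CSTF2T rose by 0.51 ± 0.13, while the nuclear poly(A)-binding protein PABPN1 fell by 0.48 ± 0.14 on the log2 scale. PABPN1 lost its call in 9 of 19 other settings (-0.58 to -0.10) and CSTF2T in 5. Control replicate 3 had 9.08 for PCF11 and 8.77 for CSTF3, whereas controls 1 and 2 had 7.74 and 7.35 for PCF11, and 7.53 and 7.13 for CSTF3. Of 16 subunits of Integrator, the complex that cuts small nuclear RNA precursors, 6 rose and 0 fell (9 over the list alone), among them INTS6 (1.06 ± 0.19) and INTS14 (1.04 ± 0.18). Of 9 histone pre-mRNA processing factors 3 rose (4 over the list alone), the cap-binding subunit NCBP1 by 0.98 ± 0.16, NPAT by 0.81 ± 0.18 and CASP8AP2 by 0.74 ± 0.16. The 45 core spliceosome genes held 11 rises and 1 fall (16 over the list alone), from AQR (1.15 ± 0.16) and PRPF4 (0.85 ± 0.17) to SNRPA1 (-0.60 ± 0.12). By camera with a preset correlation of 0.01, all 4 of these lists stood above other genes, with adjusted p = 0.00504, 0.00326, 0.0168 and 0.00585 in the order given. None held with an estimated correlation, at adjusted p = 0.658, 0.548, 0.435 and 0.661. By fry, which tests a list without setting it against other genes, the adjusted p were 0.0899, 0.0646, 0.0426 and 0.0899. Among 73 splicing regulators 10 rose and 4 fell (18 over the list alone), and the list as a whole did not shift (camera adjusted p = 0.359). PTBP2, the neural paralogue of the polypyrimidine tract-binding protein, rose by 1.10 ± 0.13 (adjusted p = 0.000644) and HNRNPM by 0.94 ± 0.13, while CLK3 and MBNL2 changed by -0.64 ± 0.15 and -0.52 ± 0.11. CLK3 lost its call in 3 of 19 other settings (-0.30 at the smallest), NPAT lost it in 2, and HNRNPM was 0.61 at the lowest. Of 14 measured replication-dependent histone genes 3 fell and 1 rose (4 over the list alone; camera adjusted p = 0.421), with H2BC21 at -1.15 ± 0.31, H2BC11 at -0.98 ± 0.21 and H1-1 at 0.54 ± 0.15. H2BC21 lost its call in 5 of 19 other settings and H1-1 in 7 of 18.

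Some genes of the integrated stress response and of the ribosome fell in the same arrays. Of 32 ATF4 and unfolded protein response genes 9 fell and 0 rose (12 called over the list alone, 11 of them lower), with a median of -0.28. They ran from DDIT4 and ATF3 to DNAJB9 (-0.50 ± 0.15) and STC2 (-0.45 ± 0.13), which lost their calls in 11 and 8 of 19 other settings. Of 66 cytosolic ribosomal protein genes 14 fell and 1 rose (26 over the list alone), with a median of -0.28. RPL17 changed by -1.18 ± 0.20 and RPL32 by -1.02 ± 0.28 (lost in 3 and 7 of 19 other settings, -0.23 and -0.35 at the smallest), and RPL27A was the exception at 1.16 ± 0.15 (0.21 and not called with the stricter filter). The list of 38 extracellular matrix and adhesion genes held 10 falls and 1 rise (14 over the list alone). The falls were led by VIM, a cytoskeletal gene placed in that list (-1.05 ± 0.12), and SPARC (from 10.33 ± 0.16 to 9.33 ± 0.07), while ITGA2 was at 0.79 ± 0.19. Of 20 cholesterol synthesis genes 6 fell (7 over the list alone), including HMGCS1 (-0.93 ± 0.25, lost in 6 of 19 other settings) and INSIG1 (-0.87 ± 0.12). Of 28 neuronal genes 4 fell, over the list alone as well, namely ENO2 (-1.33 ± 0.15), NEFL (-0.87 ± 0.12), SCG3 (-0.66 ± 0.12) and STMN2 (-0.43 ± 0.13, lost in 6 of 18 other settings). Among 29 p53 targets 6 fell and 1 rose (8 over the list alone); the growth arrest genes GADD45A, TP53INP1 and CDKN1A changed by -1.34 ± 0.21, -0.75 ± 0.12 and -0.47 ± 0.11, and TIGAR by 0.63 ± 0.16 (lost in 5 of 19 other settings). CDKN1A and ITGA2 lost their calls in 2 of 19, and SCG3 in 1 of 18. The camera test placed these 6 lists below other genes, with adjusted p = 1.25e-08, 3.48e-10, 2.46e-05, 0.00302, 0.000448 and 0.00945 in the order given. With an estimated correlation the adjusted p were 0.274, 0.435, 0.435, 0.383, 0.274 and 0.548, so none of the calls held by camera. By fry they were 0.00772, 0.0899, 0.0439, 0.0426, 0.0115 and 0.0994. Of all 22 lists fry called 7 in these arrays, among them the histone pre-mRNA processing, chaperone and epithelial lists (adjusted p = 0.0426 for each).

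Some DNA replication and chaperone genes rose. Of 45 S phase and DNA replication genes 12 rose and 0 fell (17 over the list alone), with a median of 0.22 (camera adjusted p = 0.000293; adjusted p = 0.587 with an estimated correlation). POLE2, a subunit of the leading-strand polymerase, rose by 1.03 ± 0.18, and GINS4 of the replicative helicase by 0.71 ± 0.12. Of 18 heat shock and chaperone genes 6 rose and 0 fell (10 over the list alone), HSPH1 by 0.72 ± 0.15 and DNAJA1 by 0.68 ± 0.13 (camera adjusted p = 0.0019; adjusted p = 0.435 with an estimated correlation). The 39 G2 and mitosis genes split, with 5 falls and 2 rises (8 over the list alone; camera adjusted p = 0.359). PTTG1 and UBE2C changed by -1.44 ± 0.22 (-0.88 at the smallest over settings) and -1.36 ± 0.21, and KIF11 and CENPE by 0.69 ± 0.17 and 0.57 ± 0.16 (each lost in 4 of 19 other settings). Interferon response genes held 2 rises and 2 falls among 32 (4 over the list alone; camera adjusted p = 0.496), from DTX3L (0.90 ± 0.16) to BST2 (-0.61 ± 0.15; lost in 3 of 19 other settings, -0.21 at the smallest). Nuclear oxidative phosphorylation genes held 1 rise and 1 fall among 52 (1 over the list alone; camera adjusted p = 0.542), NDUFA9 at 0.53 ± 0.12 and COX8A at -0.45 ± 0.14 (lost in 11 of 19 other settings). Of 27 genes with exons known to be regulated by RBFOX proteins, 2 rose and 3 fell at gene level (5 over the list alone; camera adjusted p = 0.97), among them fibronectin FN1 (-0.86 ± 0.14). Lists of cell type markers were measured as well. Of 9 keratinocyte and simple epithelium markers KRT8 (-0.57 ± 0.13) and CDH1 (-0.55 ± 0.16, lost in 7 of 19 other settings) fell, 2 over the list alone (camera adjusted p = 0.0161, adjusted p = 0.323 with an estimated correlation). CDH1 was at 9.51 ± 0.33 on the control arrays and is also in the extracellular matrix and adhesion list, so its fall is not read as a sign of other cells. None of 11 fibroblast, 7 blood cell and 8 endothelial markers was called, over all genes or over the list alone (camera adjusted p = 0.542, 0.632 and 0.263). The lowest unadjusted camera p of these 3 lists was 0.167. NDUFA9 and KRT8 lost their calls in 2 of 19 other settings.

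**Figure D2:**
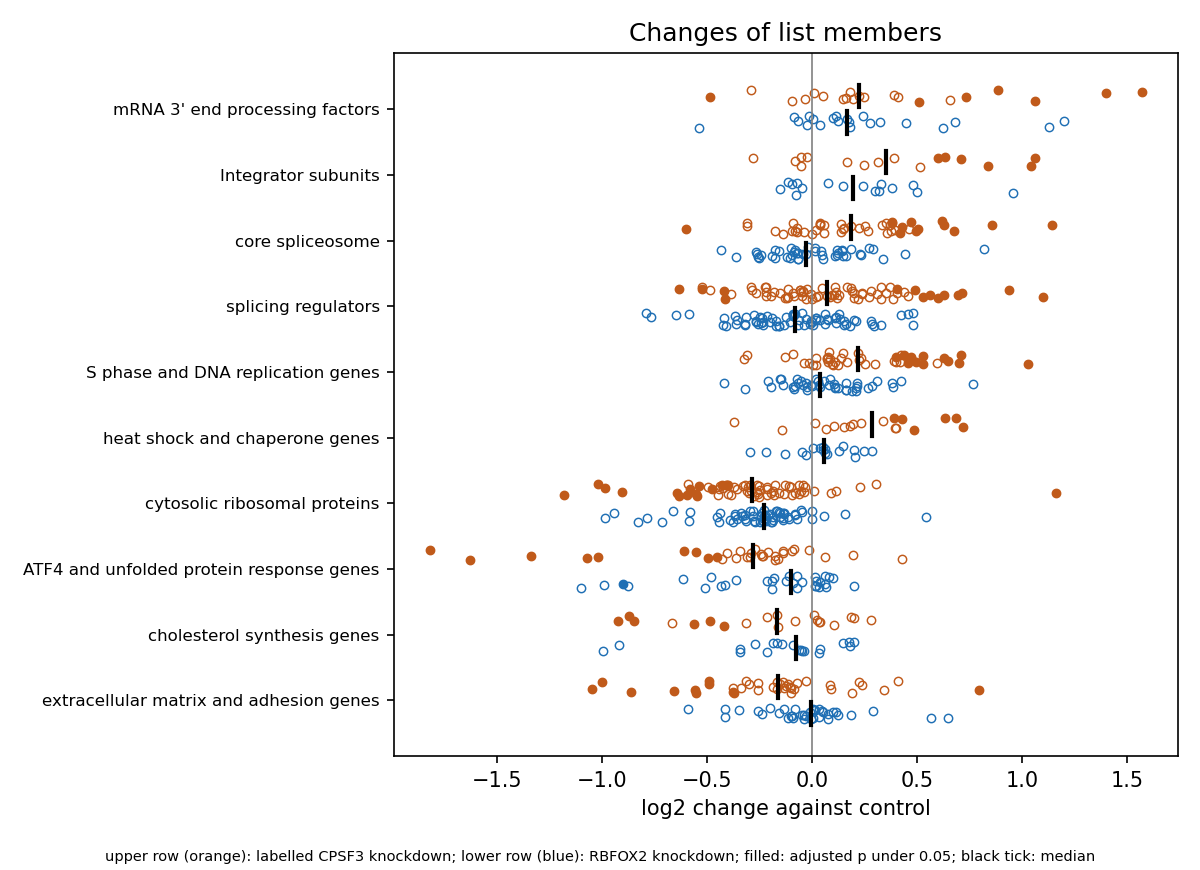
Log2 change against control (horizontal axis) of each measured member of 10 gene lists (vertical axis), in the arrays labelled CPSF3 knockdown (orange, upper) and the RBFOX2 knockdown (blue, lower). Filled points passed an adjusted p of 0.05 over all genes and the black tick is the list median; 14 ribosomal protein genes fell in the arrays labelled CPSF3 knockdown and 12 S phase genes rose.

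At the level of single exons, the signal of each probe set was taken relative to its gene on the same array. For the arrays labelled CPSF3 knockdown against control, 0 of 257548 exon probe sets passed the limma test (smallest adjusted p = 0.0603), while 32595 (12.7%) had an unadjusted p under 0.05. The probe sets nearest to the threshold had large shifts. The named exons are those that passed when the gene level was the mean over probe sets instead of the median, a setting that called 678 exons in 541 genes, 242 higher and 436 lower. Among the largest falls in relative exon signal there were those in CDC16 (ps3503184, a subunit of the anaphase-promoting complex), at -2.44 ± 0.34, HNRNPD (ps2775473, -2.09 ± 0.36), ECT2 (ps2652718, -2.09 ± 0.22) and ATP13A3 (ps2711691, -2.06 ± 0.23). The highest shifts upward were in DIDO1 (ps3913529, 2.70 ± 0.35), CDK13 (ps2998614, 2.13 ± 0.34), VPS53 (ps3739659, 2.04 ± 0.23), DOK3 (ps2888880, 1.89 ± 0.23) and RPL27A (ps3319619, 1.88 ± 0.27). Their adjusted p lay between 0.018 and 0.0466 with the mean and between 0.0603 and 0.102 with the median, where the RPL27A exon shifted by only 1.00 ± 0.20. By diffSplice each of these exons also shifted the same way in the RBFOX2 knockdown, by 1.99 in DIDO1, -1.62 in HNRNPD and 0.80 in DOK3. Both comparisons use the same control arrays. Except in DOK3, these spread more than the arrays labelled CPSF3 knockdown (SD 0.90 against 0.07 in DIDO1). The shifts are therefore not read as particular to the arrays labelled CPSF3 knockdown. The exon count depended on the test and on 1 array. It was 3799 by diffSplice, 773 with a variance trend, 1936 with array weights, and 3825 with the main test once control replicate 3 was left out. On unchanged simulated groups diffSplice called 890 exons on average, so its counts are not read as changed exons. Over single probe sets, with or without a gene, 11088 of 692116 differed from control, 7016 higher and 4072 lower. Without control replicate 1, control replicate 2, or CPSF3 replicate 1, 2 or 3 that count was 106, 279, 116, 229 or 127; it was 6331 without RBFOX2 replicate 2 and 40520 without control replicate 3. The excess of rises turned into an excess of falls in those first 5 settings (22 to 84, 56 to 223, 10 to 106, 83 to 146 and 23 to 104) and without a filter (17 to 57), so it is not read as a result. The position of each probe set within its gene is not given in the sources used here.

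The RBFOX2 knockdown changed fewer genes. Against control, 29 genes differed, 5 higher and 24 lower, and 2284 had an unadjusted p under 0.05. The balance of rises and falls is not settled: it was 1177 to 369 without control replicate 3, 953 to 560 with array weights and 68 to 69 with the replicate block. CGA, the common alpha subunit of the glycoprotein hormones, fell most, by 1.61 ± 0.13 on the log2 scale (3.05-fold; adjusted p = 6.93e-05). NKIRAS2, an inhibitor of NF-kappaB activation, changed by -1.14 ± 0.13 (adjusted p = 0.00257). Both passed the test under each of 19 other settings. Further falls were those of TXNIP at -1.35 ± 0.24, HILPDA at -1.20 ± 0.20, the neuronal enolase ENO2 at -0.92 ± 0.15, DDIT4 at -0.90 ± 0.12 and the collagen cross-linking enzyme LOX at -0.89 ± 0.16. NRN1, the junction protein F11R and the Mediator subunit MED10 changed by -1.07 ± 0.15, -0.90 ± 0.13 and -0.90 ± 0.16. The 4 named rises were GLT8D2 (1.09 ± 0.18), TULP3, a ciliary trafficking gene (1.05 ± 0.14), TNMD (1.02 ± 0.13) and PCNX4 (0.89 ± 0.16). Most of these calls were unstable. Of 19 other settings MED10 and PCNX4 lost theirs in 13, GLT8D2 in 11, TXNIP and LOX in 10, HILPDA in 8, ENO2 in 7, F11R in 6, NRN1 in 5, and DDIT4 and TULP3 in 2; TNMD lost it in 3 of 18. At the smallest NRN1 was at -0.39, GLT8D2 at 0.57 and TNMD at 0.63. Adjusted p for genes other than CGA and NKIRAS2 lay between 0.00714 and 0.048 for those named. The count was 2, 9 and 1546 without control replicates 1, 2 and 3, and 7 and 2 without RBFOX2 replicates 1 and 3. Without CPSF3 replicate 2 or 3, which enter only through the spread, it was 11 each time; with array weights it was 1513.

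Few members of the fixed lists passed on their own in the RBFOX2 knockdown, namely DDIT4 among the ATF4 genes and ENO2 among the neuronal genes. By camera with the preset correlation 11 of 22 lists shifted, 9 down and 2 up, and 0 of 22 did with an estimated correlation (lowest adjusted p = 0.274). By fry 1 of 22 passed, the ATF4 list (adjusted p = 0.0426). Ribosomal protein genes had a median of -0.23, with 62 of 66 below 0 and 10 called over the list alone (camera adjusted p = 2.4e-15; adjusted p = 0.383 with an estimated correlation). RPL17 was at -0.99 ± 0.20 and missed the threshold over all genes (adjusted p = 0.0617). Over 19 other settings it ranged from -1.24 to -0.23 and passed in 3. The ATF4 and p53 lists had medians of -0.10 and -0.06, with 9 and 7 members called over the list alone, all lower (camera adjusted p = 6.92e-06 and 7.01e-05; adjusted p = 0.274 and 0.383 with an estimated correlation). Cholesterol synthesis, splicing regulator, neuronal, oxidative phosphorylation, G2 and mitosis, and epithelial genes also lay below other genes, at camera adjusted p = 0.00831, 0.00671, 0.0168, 0.0168, 0.035 and 0.0385. Their adjusted p with an estimated correlation were 0.435, 0.661, 0.383, 0.661, 0.708 and 0.383. Over the list alone 2, 3, 4, 0, 2 and 1 members of these 6 lists were called. Factors of 3' end processing and Integrator subunits lay above other genes (camera adjusted p = 0.0168 and 0.0484; adjusted p = 0.67 for both with an estimated correlation), with 4 and 1 members called over the list alone. INTS14, at 0.96 ± 0.18, came nearest to the threshold over all genes (adjusted p = 0.0504). The other 11 lists did not shift, with camera adjusted p from 0.086 to 0.926.

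For exons in the RBFOX2 knockdown, the limma test called 0 of 257548 probe sets (smallest adjusted p = 0.254), with 20306 (7.88%) at an unadjusted p under 0.05. With the mean as gene level 1 exon passed, in GOLIM4 (ps2704289), at -1.95 ± 0.17 (adjusted p = 0.0331). diffSplice called 919, near the 862.7 it called on average in unchanged simulated groups, and without control replicate 3 the main test called 823. In the genes whose exons RBFOX proteins are known to regulate, 902 exon probe sets in 27 genes were tested, and 94 had an unadjusted p under 0.05. Adjusted over the list alone, which was chosen after the test over all exons had called 0, 4 passed, all lower (adjusted p = 0.405 over all exons for each). The list names genes, and the exon that each probe set reads is not given in the sources used here. Whether any of the 4 reads an exon that RBFOX proteins regulate therefore cannot be told. In FN1 (ps2598321) the exon signal relative to the gene was 0.00 ± 0.04 on the control arrays and -1.11 ± 0.15 on the RBFOX2 knockdown arrays (adjusted p = 0.0124 over the list alone). The exon in ECT2 (ps2652718) went from -0.39 ± 0.18 to -1.80 ± 0.48 (adjusted p = 0.034), that in the cytoskeletal gene EPB41 (ps2327732) from -0.90 ± 0.18 to -1.76 ± 0.16 (adjusted p = 0.034), and that in the kinase MAP3K7 (ps2964806) from -0.49 ± 0.27 to -1.42 ± 0.15 (adjusted p = 0.0397). All 3 RBFOX2 arrays lay below all 3 control arrays for each of the 4 exons, which adds no support, since the exons were chosen on these arrays. The same 4 exons passed over the list alone in the arrays labelled CPSF3 knockdown, where their means were -0.79 ± 0.23 (FN1), -2.17 ± 0.16 (ECT2), -2.09 ± 0.13 (EPB41) and -1.37 ± 0.16 (MAP3K7). Both comparisons use the same 3 control arrays, which alone gave exon changes a correlation of 0.5 in simulated unchanged groups, so the shared direction is not a separate finding. That comparison called 10 exons of the list, 8 lower and 2 higher, the other 6 being 2 more in ECT2 (1 of them higher), 2 in PTBP2, 1 in SPTAN1 and 1, higher, in MEF2C. The 4 changes stayed downward in both comparisons without any one array. This had to be so, since all arrays of both targeted groups lay below all control arrays for these exons. In the RBFOX2 comparison 0 of the 4 stayed called without control replicate 1 or 2 or RBFOX2 replicate 1 or 3, 1 without any one CPSF3 array, 2 without RBFOX2 replicate 2 and 4 without control replicate 3. In the comparison of the arrays labelled CPSF3 knockdown 2 to 4 of the 4 stayed called.

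**Figure D3:**
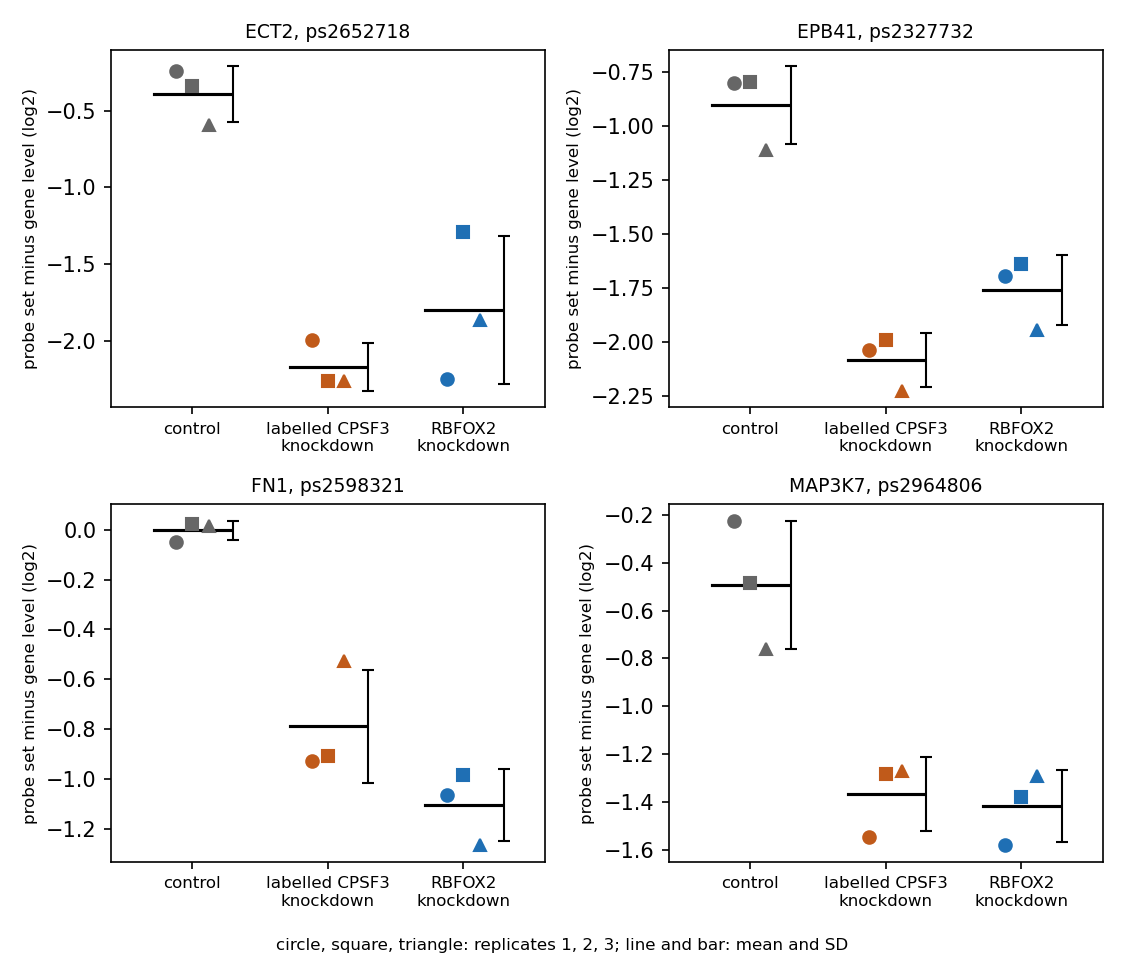
Probe set signal minus gene level (log2, vertical axis) for 4 exon probe sets by group (horizontal axis); symbols are replicates, the line is the mean and the bar the SD. In each panel all arrays of both targeted groups lie below the control arrays, as in FN1, where the means are 0.00 (control), -0.79 (labelled CPSF3 knockdown) and -1.11 (RBFOX2 knockdown). The exons were chosen by their p on these same arrays, and whether they are the exons that RBFOX proteins regulate cannot be told.

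Set directly against each other, the arrays labelled CPSF3 knockdown and the RBFOX2 knockdown arrays differed at 67 genes, 23 higher and 44 lower in the former. That balance is not settled, at 38 to 33 without RBFOX2 replicate 3 and 296 to 305 with array weights. CGA (1.39 ± 0.13) and PTBP2 (1.37 ± 0.13), both at adjusted p = 0.000442, were higher in the arrays labelled CPSF3 knockdown, followed by NKIRAS2 (1.19 ± 0.13), TTPAL (1.17 ± 0.21) and PRKXP1 (1.07 ± 0.21). PTBP2 was at 10.06 ± 0.12 in control, 11.16 ± 0.10 in the arrays labelled CPSF3 knockdown and 9.79 ± 0.22 in the RBFOX2 knockdown. STC1 (-1.52 ± 0.23), the integrin ligand EDIL3 (-1.27 ± 0.15), the peptidase DPP4 (-1.25 ± 0.13), ARRDC4 (-1.22 ± 0.23) and the depalmitoylating enzyme LYPLA1 (-1.16 ± 0.15) were lower there. ARRDC4, TTPAL, PRKXP1 and STC1 lost their calls in 8, 9, 8 and 3 of 19 other settings, and TTPAL was 0.59 at the lowest. By camera 6 lists were higher in the arrays labelled CPSF3 knockdown. These were core spliceosome (adjusted p = 2.07e-06), S phase (2.61e-06), splicing regulator (1.36e-05), chaperone (2.35e-05), histone pre-mRNA processing (0.00269) and Integrator genes (0.00881). The 4 lower lists were extracellular matrix (adjusted p = 2.07e-06), ATF4 (7.96e-05), neuronal (0.00269) and fibroblast marker genes (0.0139). With an estimated correlation 0 of these 10 held (lowest adjusted p = 0.312), and fry called 0 lists. Ribosomal protein genes did not differ by this test (camera adjusted p = 0.226). No exon passed by limma (smallest adjusted p = 0.7; 10931 at an unadjusted p under 0.05; 79 by diffSplice). The gene count was 149 when only these groups entered the fit, 140 with the mean as gene level, 18 without a signal filter, 42 with the replicate number as a block and 601 with array weights. Without control replicate 1 or 3, CPSF3 replicate 1, 2 or 3, or RBFOX2 replicate 1 or 2 it was 28, 145, 14, 17, 24, 28 or 15.

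The changes of the targeted groups were compared across genes. Of the 29 genes called in the RBFOX2 knockdown, 22 were also called in the arrays labelled CPSF3 knockdown, all in the same direction, 19 lower and 3 higher. Independent lists would share 1.05 lower and 0.5 higher. Ranked by the smaller of their changes, TXNIP, HILPDA, NRN1, TULP3 and ENO2 came first. Across 16748 genes, which are not independent replicates, the log2 changes correlated at 0.768 with a covariance of 0.0534. Both comparisons use the same control arrays, and unchanged groups simulated against shared controls gave a correlation of 0.5 (0.471 to 0.519 in 100 simulations), and a covariance of 0.0114. In 20 further simulations 0 and 0.05 genes were called on average, too few to set the 22 shared genes against. The covariance exceeded the simulated one by 0.042. For exons relative to their gene the correlation was 0.735 against 0.5 simulated, and the covariance exceeded the simulated one by 0.0268. In the simulations each gene or exon was drawn independently, with the same spread in all 3 groups. On the real arrays control replicate 3 differed from the other controls across many genes. Shared controls may therefore give more than the simulated values, and the excess is not read as a common effect. A group of 3 controls cannot be divided into parts of 2, and part of the shared calls may come from the shared controls. The correlation was 0.836 without control replicate 3 and 0.64 without RBFOX2 replicate 3. The number of shared genes was 5 without a signal filter and 13 with arrays centred on their medians.

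**Figure D4:**
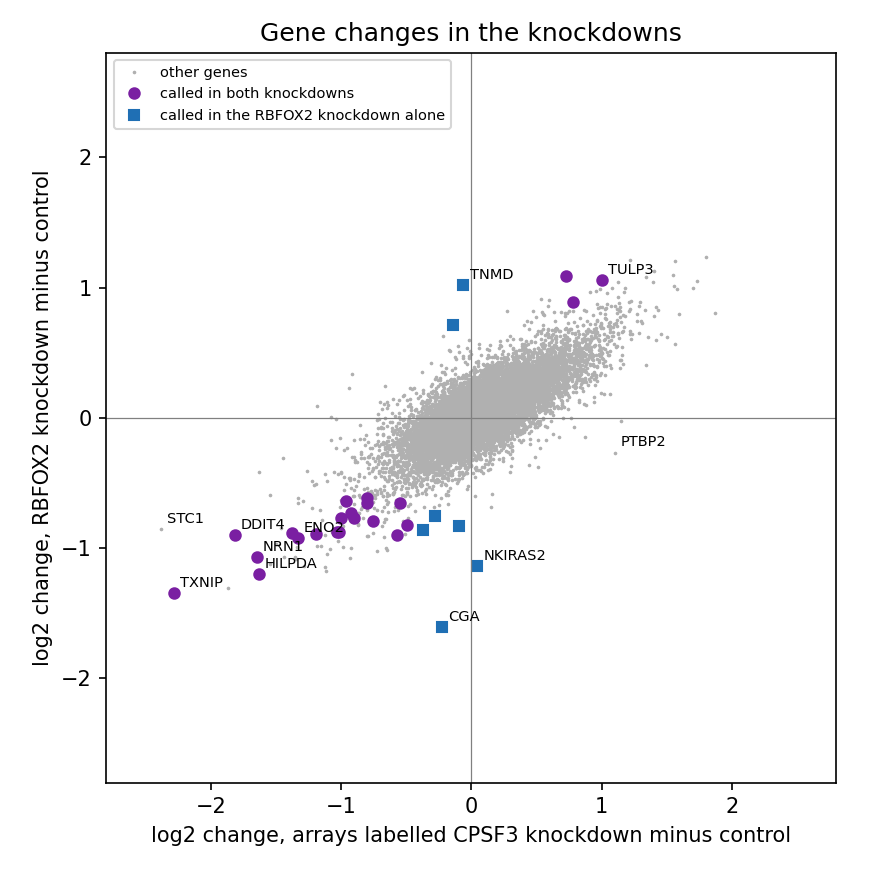
Log2 change of each of 16748 genes in the arrays labelled CPSF3 knockdown (horizontal axis) and in the RBFOX2 knockdown (vertical axis), both against the same 3 control arrays. The 22 genes called in both lie in the same direction, while CGA, NKIRAS2 and TNMD changed in the RBFOX2 knockdown and lie near 0 on the horizontal axis.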

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

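The exon run without probe sets at 0, the overlap under other gene summaries and exon tests, the correlation without single arrays and the adjustment over the exons of the RBFOX list alone were chosen after seeing the data; the other alternatives were planned. The cause of each difference below was not tested. Among named genes and lists, no called value changed the direction of its test, and other genes, exons and probe sets were not followed. The median of the G2 and mitosis list in the RBFOX2 knockdown ranged from -0.0907 to 0.0492. The comparison of gene ends was not run. Leaving out 1 array at a time, changed genes ranged from 965 to 3429 for the arrays labelled CPSF3 knockdown, from 2 to 1546 for the RBFOX2 knockdown and from 14 to 145 between the targeted groups. Changed exons ranged from 0 to 3825 and from 0 to 823 in the comparisons with control and stayed at 0 between the targeted groups, and changed probe sets from 106 to 40520 and from 0 to 18869. The highest of each of these counts that changed came from leaving out control replicate 3. The CPSF3 change ranged from -0.20 to 0.07, so its sign is not settled, and was never called, and the RBFOX2 change from -0.66 (past the threshold, without control replicate 3) to -0.52. The correlation of the targeted groups ranged from 0.64 to 0.836, and shifted lists from 13 to 13 and from 5 to 12.

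Without a signal filter, 7 genes changed in the RBFOX2 knockdown, 18 between the targeted groups and 5 in both; 74 and 0 probe sets changed in the comparisons with control. The stricter filter gave 2 exons and 18046 probe sets for the arrays labelled CPSF3 knockdown and 23 probe sets for the RBFOX2 knockdown, and RBFOX2 then passed at -0.67. Centred arrays gave 19 RBFOX2 genes and 13 shared. Only the compared groups gave 5 RBFOX2 genes, 149 between the targeted groups and 0 RBFOX2 probe sets. The variance trend gave 773 exons, and 22205 and 38 probe sets. Array weights gave 4817, 1513 and 601 genes, 1936 exons, 36062 and 6 probe sets, and RBFOX2 at -0.69, past the threshold. The mean as gene level gave 44 RBFOX2 genes, 140 between the targeted groups, 34 shared, 678 and 1 exons with 1 shared, and RBFOX2 at -0.56, past the threshold. diffSplice gave 3799, 919 and 79 exons with 673 shared; in unchanged simulated groups it called 890 and 862.7 with 162.5 shared. Without probe sets at 0 on every array, 199 exons were called. Adjusted over the list alone, 10 and 4 exons of the RBFOX list were called against 0 and 0. Among genes changed by under 0.5, the targeted groups correlated at 0.615. With an estimated correlation 0 lists shifted in the comparison of the arrays labelled CPSF3 knockdown and 0 in the RBFOX2 comparison. Whether replicate numbers pair these arrays is not settled. Of 9 pairs with the same number 3 deviated together (correlation over 0.1, range -0.143 to 0.332), and 4 arrays correlated best with their own number. With the replicate block 137 genes changed in the RBFOX2 knockdown and 42 between the targeted groups, RBFOX2 passed at -0.58, and 0 RBFOX2 probe sets were called. Quantile normalisation moved no total by over 1.5 times. For named genes, 2139 values kept their side of the threshold, 342 lost it and 53 gained it; for lists, 605 kept it, 49 lost it and 4 gained it.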

Other observations

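The gene lists in this part were written after the gene changes were seen, leaving out members already seen among the leading genes. Of 66 ribosome biogenesis genes, 31 rose and 0 fell in the arrays labelled CPSF3 knockdown (41 called over the list alone), with a median of 0.43, opposite to the ribosomal protein genes. The list stood above other genes by camera (adjusted p = 1.98e-12; adjusted p = 0.19 with an estimated correlation). HEATR1 rose by 1.07, DDX18 by 0.98, UTP3 by 0.96 and the RNA polymerase I subunit POLR1A by 0.84. In the RBFOX2 knockdown the list also lay above other genes, with a median of 0.12, 46 of 66 above 0 and 0 members called, 4 over the list alone (camera adjusted p = 0.00709; adjusted p = 0.494 with an estimated correlation), and the direct contrast of the targeted groups had a median of 0.31 (camera adjusted p = 4.51e-16; adjusted p = 0.264 with an estimated correlation). Host genes of small nucleolar RNAs lay low in both targeted groups, with medians of -0.31 and -0.40 over 16 genes (camera adjusted p = 0.0025 and 1.97e-07; adjusted p = 0.294 and 0.117 with an estimated correlation). Of these, SNHG15 (-0.94) and EIF4A2 (-0.86) fell in the arrays labelled CPSF3 knockdown, and SNHG20 rose (0.90). Among 426 zinc finger genes named ZNF and a number, 87 rose and 8 fell in those arrays (median 0.18; camera adjusted p = 1.62e-06; adjusted p = 0.294 with an estimated correlation). In the RBFOX2 knockdown 0 were called, with a median of 0.09 and 279 above 0 (camera adjusted p = 0.00354; adjusted p = 0.494 with an estimated correlation).

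A list of hypoxia-responsive genes lay below other genes by camera in both targeted groups. Of 34 such genes, 11 fell and 0 rose in the arrays labelled CPSF3 knockdown, with NDRG1 at -0.94, PDK1 at -0.70, BNIP3 at -0.59 and VEGFA at -0.50. The list medians were -0.22 there and -0.25 in the RBFOX2 knockdown, where 28 of 34 lay below 0 and 0 were called over all genes, 11 over the list alone (camera adjusted p = 2.63e-07 and 1.58e-10). With an estimated correlation the adjusted p were 0.0289 and 0.0198, over 8 tests against 44 for the lists written beforehand. Before adjustment the ATF4 list had nearly the same camera value in the arrays labelled CPSF3 knockdown (0.00748 against 0.00723), so the hypoxia list does not stand apart there. The targeted groups did not pass against each other by camera (adjusted p = 0.217). The median was below 0 against each control array taken alone, the highest of the 6 values being -0.208, which argues against 1 deviating control array. It also lay below the lowest 2.5% of 10000 random lists matched on signal level, at -0.0536 in the RBFOX2 knockdown, which argues against a normalisation trend with signal. An open hypothesis is that the control cultures may have been denser or less well supplied with oxygen than those of both targeted groups. Another is that both hairpins lower this response. TXNIP, which glucose induces, was higher on the control arrays than in both targeted groups, so a shortage of glucose in the controls is not proposed. No label records culture density, so the 2 hypotheses cannot be separated here. Arrays of control and targeted cultures matched for density and medium would decide between them.

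The control arrays were not alike: control replicate 3 correlated best with RBFOX2 replicate 2 (0.979 across genes). With RBFOX2 replicates 1 and 3 it correlated at 0.965 and 0.963, above the 0.957 and 0.939 with control replicates 1 and 2. By its median position over called genes, given below, it lay between the other controls and the targeted groups, closer to the RBFOX2 arrays. The test of RBFOX2 levels and the held-out test were chosen after the result was seen, the other position tests before. Its RBFOX2 level, 3.87 SD above the mean of the RBFOX2 arrays, speaks against a wrong label as an RBFOX2 array, but rests on that gene alone. On a scale from controls 1 and 2 (0) to the RBFOX2 arrays (1), its median position was 0.849, with an upper quartile of 1.03. That was over the 1546 genes called in the RBFOX2 knockdown without it, and over the 823 exons the median was 0.805. No RBFOX2 array was held out for comparison, so a wrong label as an RBFOX2 array stays open. A wrong label as a CPSF3 array is argued against by its median position of 0.54 on a scale from controls 1 and 2 (0) to those arrays (1), with an upper quartile of 0.771, over the 3429 genes called without it. That choice of genes alone would keep any further array below 1, so each CPSF3 array was also held out in turn, with genes called from the other arrays without control replicate 3. The held-out arrays lay at medians of 1.16, 0.875 and 0.827, and control replicate 3 at 0.583, 0.518 and 0.517 over the same genes, with upper quartiles of 0.815, 0.732 and 0.732. Measured against control replicate 3 alone, a median share of 0.46 of the change was left for those genes, 0.151 for the 1546 genes and 0.195 for the 823 exons called in the RBFOX2 knockdown without it. Selection on controls 1 and 2 lowers these shares, so whether a difference between arrays unrelated to the hairpins could account for those RBFOX2 calls cannot be told apart from a knockdown effect; controls from a single known batch would settle it.

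The CPSF3 transcript was not measurably lower in the arrays labelled CPSF3 knockdown, and the tests of this were chosen after the result was seen. Exchanged labels of the targeted groups are argued against by RBFOX2, which was higher by 0.388 in the arrays labelled CPSF3 knockdown than in the RBFOX2 arrays. A gene summary that hides large falls of probe sets is argued against by the 0 of 21 probe sets lower at an unadjusted p under 0.05. With 19 of the 21 lower in mean, a small fall shared by most probe sets is not excluded. A fall by 1 or more on the log2 scale is argued against by the lower bound of the 95% interval, -0.429. Open hypotheses are a weaker knockdown, transcript that had recovered by day 10 in cells that outgrew those with low CPSF3, or a hairpin acting on protein more than on RNA; the arrays may hold changes from any of these or from effects on other targets, and protein was not analysed here.

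Other groupings of the same 6 arrays, 10 per comparison with the real one included, cannot give a share under 0.1, too few for a value under 0.05. What they would show was written down after the counts were seen. For genes, 1 of 10 splits gave as many calls as the real one in each comparison: 2409 against a highest other of 0, 29 against 1, and 67 against 0. For probe sets 1 of 10 did as well, with 11088 against 0 and 3 against 1. For exons all 10 splits gave 0 in each of the 3 comparisons. By diffSplice the real counts of 3799, 919 and 79 stood beside highest others of 528, 1442 and 1490.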
